A study of Mus musculus with 5 samples.

How the data were processed

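Total RNA from 5 cultures of mouse embryonic fibroblasts was sequenced on an Illumina platform per the labels' protocols, with 1 library each for EV, M, P, MP and WT. Groups were taken from the sample labels. The authors deposited 4 tables, each setting EV against 1 other library, with 61082 loci per table. The submitters' processing notes name TopHat, Cufflinks, Cuffdiff and the mm9 genome build. Their versions, the annotation, read filters and the library normalisation method were not given in the sources used here. Values are FPKM per locus, estimated by the authors per the file headers and these notes. FPKM is by definition fragments per kilobase of transcript, scaled to the number of fragments mapped. The sums given below for EV and M exceed what that scale allows. The deposited p-value and q-value columns are those of the authors' test of 1 library against 1, and loci counted as called are those the authors marked significant, which were those with q under 0.05. Many loci had a test status other than OK: 8071 single-gene loci of the M comparison were marked FAIL.

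Of the loci, 37277 carried no gene symbol and 911 joined several genes, and both kinds were left out. The other 22894 loci held 21372 symbols. Where a symbol had several loci (1154 symbols), the locus with the highest mean log2(FPKM + 1) was used. Genes with near-identical copies, such as the class I, histone, Olfr and Vmn families, are uncertain, because how shared reads were assigned is not given in the sources used here. Strand and gene overlap were not considered. EV values were taken from the same table as the library compared. The EV columns of the MP, P and WT tables differed from that of the M table by 1 factor each (0.972, 1.10 and 1.12), within 1% at 99.4% of loci or more. MP against M and MP against P were set across tables, on deposited values as the difference of the log2 ratios to EV and on scaled values directly.

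The rule fixed before the data were examined kept a gene at 1 FPKM or more in 1 of the 2 libraries and called a gene 2-fold apart where log2((FPKM + 1)/(FPKM + 1)) was at least 1 in size, on the values as deposited. This scale understates changes of genes with low values. Because the libraries differed in level by up to 44.3-fold, each library was also scaled so that its upper quartile, over genes at 1 FPKM or more in any library, was 10, and the same rules were applied to these units. For gene counts and for Meis1 and Pknox1 this scaling was planned. For lists, overlaps, correlations and named genes it was chosen after seeing the data, and it leads the text because the deposited ratios mainly give the shift of a whole library. On it, the EV column of the M table was used throughout.

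The range of the values was narrow: the 99th percentile was 2.01 times the upper quartile in EV, 1.98 in M, 1.78 in P, 1.88 in MP and 1.72 in WT, and at least 97.3% of the genes at 5 scaled units or more lay between 5 and 20. Differences between genes well expressed in both libraries are therefore compressed. Genes listed at 0 made up 2.18% in EV, 9.37% in M, 24.6% in P, 27.5% in MP and 22.0% in WT. No counts or depths were given, so no counting interval could be made. Loci without a gene symbol that were above 0 in both libraries of a pair were searched for steps of single reads. The commonest ratio to MP at these loci was 163 for M, 0.642 for P and 0.883 for WT, against level ratios of 44.3, 1.19 and 1.24. EV showed no clear step (60 loci at the commonest ratio), so relative depth was not recovered for EV.

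Named genes were, per comparison with EV, the 8 highest and 8 lowest log2 ratios among genes at 5 or more in 1 of the 2 libraries with the authors' status OK, and 5 and 5 for the pairs across tables. Some of the named genes are not reported here. Names starting with Gm and a digit, Mir, Snor, LOC or n-R, names ending in Rik and joined loci were left out. The rule was applied to deposited values as fixed and to scaled values as an addition, without the status condition. Meis1, Pknox1 and other TALE genes, and the members of a described list with the largest changes, were named as well. Genes named for being on or off in WT alone, and Axin2, Wnt10a, Pi15 and Acan where singled out, were chosen after their values were seen.

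The 35 gene lists (pathways, complexes and markers of other cell types) were fixed before the data were examined. A list's median log2 ratio was set against 10000 random lists of equal size matched on mean expression in 20 bins. A list with at least 5 kept members stood apart under percentile 2.5 or over 97.5, so chance gives about 1.75 of 35 lists per pair. On scaled values 17 of 32 lists stood apart in M against EV, 14 of 32 in P, 12 of 32 in MP, 15 of 32 in WT, 9 of 32 in MP against M and 7 of 32 in MP against P. Percentiles describe these libraries and are not tests. For M and P against the shared EV, each gene's 3 values were reassigned among the libraries in 1000 draws. Alternatives were a pseudocount of 0.1, no filter, a filter at 5, centring on the median log2 ratio, upper-quartile scaling and means of list members.

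The rules were tested on simulated data modelled on M against EV (10954 genes kept, log2 noise SD 0.157), with 200 changed genes. All 100 genes changed 4-fold were recovered, 22 of 100 changed 2-fold, because the pseudocount takes a 2-fold change under the threshold, and 0 unchanged genes were called. The changed genes all stood at 5 scaled units or more in EV. The noise SD came from genes at 5 or more in both libraries and was applied to every gene. Noise of that size could hardly reach the threshold of 1, so the 0 does not cover the noisier genes of low value. Of 200 random lists of 20 members, 9 (4.50%) were called without a shift and 199 with a shift of 1 noise SD. Noise was independent between genes, so this does not cover lists whose genes vary together. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A mouse annotation of another genome build gave transcript lengths (19953 symbols, 93.4%) and chromosomes by symbol alone, and no coordinates were used.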

Results

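RNA-seq expression values were compared for mouse embryonic fibroblasts (MEFs, primary connective-tissue cells cultured from embryos) that differed in the TALE homeobox transcription factors Meis1 and Prep1. Prep1 is encoded by Pknox1. The 5 libraries comprised 4 lines made from Prep1-hypomorphic MEFs, which carry an allele of reduced Prep1 expression, and 1 wild-type line (WT). The hypomorphic lines had been infected with an empty vector (EV) or made to overexpress Meis1 (M), Prep1 (P) or both (MP). All cells were C57BL/6 at passage 30 per the labels. Each group held 1 library, so no difference has a replicate check, no p-value was computed across genes, and every comparison is between libraries rather than conditions. Read depth is unknown. Levels are given in scaled units, FPKM after setting the upper quartile of genes in each library to 10, and differences as log2((level + 1)/(level + 1)).

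Meis1 followed the labels and Pknox1 did not. Meis1 (XLOC_005789) stood at 16.1 scaled units in M and 14.7 in MP, against 7.91 in EV, 8.55 in P and 12.0 in WT, which gave log2 ratios over EV of 0.94 for M, 0.82 for MP, 0.10 for P and 0.54 for WT. Pknox1 (XLOC_022130) stood at 10.7 in WT, 2.06 in EV and 3.11 in M, so the hypomorphic EV line held 19.3% of the WT level. In the libraries labelled as overexpressing Prep1, Pknox1 stood at 0.534 in P and 0.542 in MP. These levels were 26% and 26.3% of EV, and 5.0% and 5.07% of WT. The values therefore go against the labels P and MP, and every direction drawn below from the library labelled P or the library labelled MP carries that limit. Among other TALE genes, Meis3 stood at 11.8 in WT and 3.38 in EV, and Meis2 at 17.8 and 8.80. As deposited, without scaling, the log2 ratio of Meis1 over EV was 2.45 in M, -3.69 in P, -3.01 in MP and -3.20 in WT, and that of Pknox1 was 2.00, -4.55, -4.46 and -1.44.

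**Figure D1:**
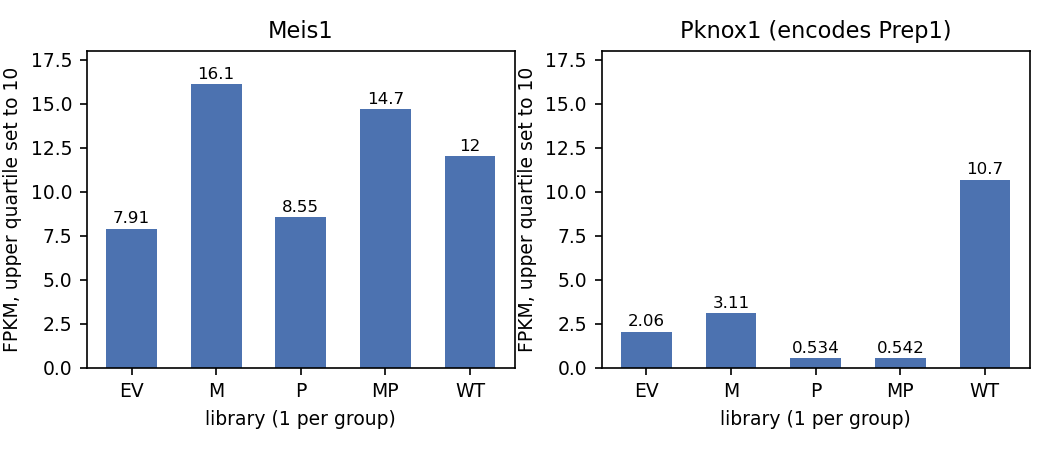
Levels of Meis1 and Pknox1 in each of the 5 libraries, in FPKM after setting the upper quartile of genes to 10 (y axis), with 1 bar per library. Meis1 is highest in M (16.1) and MP (14.7), whereas Pknox1 is highest in WT (10.7) and lowest in P (0.534) and MP (0.542).

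The deposited values of EV and M lay far above those of the other libraries at nearly every gene. The upper quartile was 165 FPKM in EV and 448 in M, but 12.0 in P, 10.1 in MP and 12.5 in WT. The median log2 ratio to EV, over genes at 5 FPKM or more in both libraries, was 1.37 for M, -3.86 for P, -3.89 for MP and -3.84 for WT. With the values as deposited, 12906 genes were at least 2-fold higher and 2579 lower in M than EV, 12 and 20839 in P, 0 and 20816 in MP, and 16 and 20544 in WT. The authors' deposited tables called 1004 single-gene loci higher and 3 lower in M, 1 and 9912 in P, 1 and 9437 in MP, and 11 and 10205 in WT. Over all loci, those without a gene name included, 1210 were called higher and 1332 lower in M. Differences are reported relative to these shifts, on the scaled values. Genes of the olfactory (Olfr) and vomeronasal (Vmn) receptor families, which act in sensory neurons of the nose, were above 0 in 99.9% of 1396 cases in EV and 69.9% in M, against 10.6% in P, 12.6% in MP and 16.6% in WT. The same 2 libraries, EV and M, thus carried both the higher level and the signal at receptor genes.

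**Figure D2:**
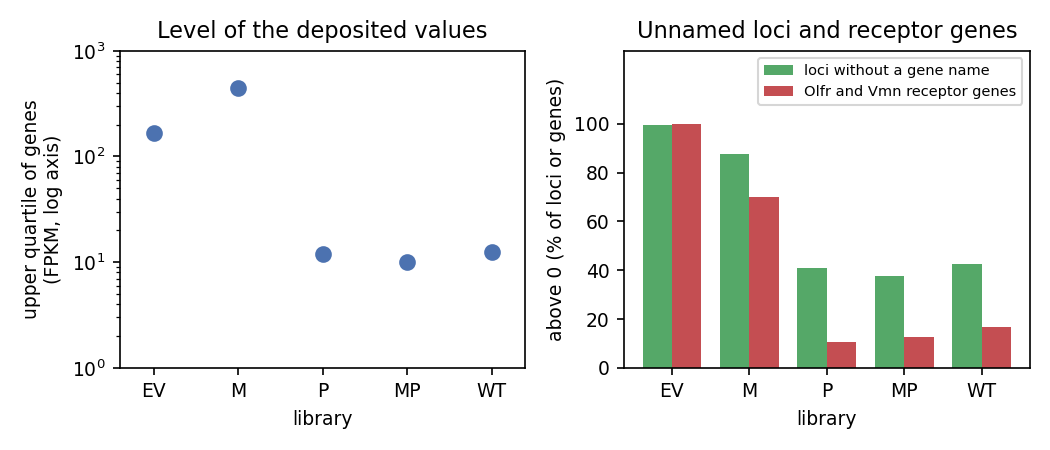
Left, upper quartile of genes in FPKM on a log axis for each library, with 1 point per library. Right, percent of loci without a gene name and of Olfr and Vmn receptor genes above 0 in each library: EV and M stand above P, MP and WT in both panels, for example 99.5% of unnamed loci in EV and 37.5% in MP.

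The comparison of M with EV asked what added Meis1 changes when Prep1 is low. Fgf10, a growth factor of limb and lung buds, stood at 5.20 scaled units in M and 1.80 in EV (log2 1.15), Pdgfra, a receptor marking mesenchymal fibroblasts, at 6.26 and 2.43 (1.08), Pi15 at 22.3 and 9.26 (1.18), and Tnfsf11, the osteoclast factor RANKL, at 5.25 and 1.95 (1.08). Hecw2 (1.24), Cpne4 (1.19), Kcnab1 (1.14) and the small RNA gene AF357355 (1.08) completed the 8 genes with the highest ratios. Acan, the cartilage proteoglycan aggrecan, was lower, at 0.974 in M and 5.15 in EV (-1.64), as were Luzp4 (-1.57), Scarna17 (-1.35), Rasgrp3 (-1.28), Gchfr (-1.11), Adam8 (-1.08), Serpinb2 (-1.06) and S100a7a (-1.06). In all, 33 genes were at least 2-fold higher and 64 lower in M, of 11039 kept.

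Among gene lists, MHC class I and antigen presentation genes (median log2 -0.40, percentile 0 among 10000 matched random lists, 1 of 12 members at least 2-fold lower) and interferon response genes (-0.31, percentile 0, 1 of 30) were lower in M. Psmb8 (-1.10) and Tap1 (-0.90), which belong to both lists, Trim30a (-0.88) and Irf7 (-0.80) moved most. AP-1 subunits, the Fos, Jun, Atf and Maf proteins that form the AP-1 dimer, had a median of -0.14 (percentile 0.66), with none of 15 members 2-fold apart and Batf3 (-0.70), Fosb (-0.67), Atf3 (-0.37) and Junb (-0.35) moving most. Immediate-early genes (-0.17, percentile 0.09) and AP-1-linked invasion genes (-0.13, percentile 0.31) were also lower in M, as were ribosomal protein (-0.27, percentile 0), myofibroblast (-0.26, percentile 0), heat shock (-0.20, percentile 0.03) and oxidative phosphorylation genes (-0.13, percentile 0.01). Growth factor genes of the IGF, FGF and PDGF families were higher (0.14, percentile 99.9), led by Fgf10, Igfbp2 (0.90) and Igfbp5 (0.80); on deposited values that list stood at percentile 96.2, inside the bounds. Ranked on deposited values instead, the genes highest over EV were Vmn2r-ps60, Sval2, Vmn1r25, Retnlg, Olfr196, Olfr855, Olfr994 and Olfr596, none above 1.87 scaled units in M, and those lowest were Scgb1b24, BC061237, S100z, Crct1, S100a8, Nupr1l, Ly86 and Otog.

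The comparison of the library labelled P with EV asked what added Prep1 changes in hypomorphic cells. Igfbp5, a secreted binding protein of insulin-like growth factors, stood at 13.4 scaled units in P and 3.24 in EV (log2 1.76). Sort1, the sorting receptor sortilin, stood at 5.52 and 0.817 (1.84), Pear1 at 7.03 and 1.13 (1.91), and Pcsk6, a proprotein convertase, at 7.16 and 1.48 (1.72). BC039966 (2.13), U90926 (1.90), Slco4a1 (1.82) and Anxa8 (1.69) were the others of the 8 highest. Lower in P were Obox3 (-2.74), Luzp4 (-2.60), Fgf14 (-2.01), Pi15 (-1.88), Tmtc2 (-1.84), Cd84 (-1.79), the class I gene H2-Q4 (-1.58) and Nlrc5 (-1.58), the transactivator of class I genes. Obox3, Luzp4 and Fgf14 were also low in WT (0.0767, 0 and 3.80 scaled units). Sort1, Pear1 and Pcsk6 were also high there (4.07, 9.35 and 5.94). At these genes added Prep1 cannot be told apart from whatever else parts EV and M from P, MP and WT. In all, 73 genes were at least 2-fold higher and 182 lower in P, of 11069 kept. With genes kept at 5 or more the counts were 40 and 53, so the excess of lower genes rested largely on low values. Pknox1 itself was lower in this library.

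MHC class I and antigen presentation genes were the list furthest below EV in the library labelled P (median log2 -1.0, percentile 0, 6 of 12 members at least 2-fold lower), led by H2-Q4, Nlrc5, Tap1 (-1.54) and Psmb8 (-1.30). Interferon response genes were lower too (-0.52, percentile 0, 3 of 30 members), with Trim30a at -1.44 and Zbp1 at -0.94. The 2 lists share 3 genes. The MHC class I list was also lower in M (-0.40) and WT (-0.42) than EV, and in MP than M (-0.70). It stood inside the bounds in WT against P (percentile 41.6) and in MP against P (percentile 89.55). Added Prep1 therefore cannot be told apart, for this list, from whatever else parts EV and M from P, MP and WT. Cell cycle genes (-0.25 against -0.14 in matched random lists, percentile 0.09), with Top2a at -0.61 and Uhrf1 at -0.54, histone genes (-0.45 against -0.15, percentile 0) and myofibroblast genes (-0.39, percentile 0), with Flna at -0.82 and Tagln at -0.68, were lower without a 2-fold member. Hox genes were higher (0.35 against 0.10, percentile 98.7, none of 8 members 2-fold), whereas that list stood at percentile 95.4 by its mean and 12.6 on deposited values. In the Wnt list, which did not stand apart, the Wnt target Axin2 was at 16.2 in P and 46.6 in EV, and Wnt10a at 2.33 and 0.270. By rank on deposited values, the genes least reduced relative to EV were Sort1, Mmp10, Wnt11, Pear1, Prl2c1, Perp, Kctd15 and Jam2, and the most reduced were Obox3, Luzp4, Speer7-ps1, Rhox8, Rex2, Fgf14, AF357426 and Pggt1b.

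The library labelled MP, with both factors added per the labels, held Igfbp5 at 13.2 scaled units and Sort1 at 5.43, close to P and above EV (log2 1.74 and 1.82). Akr1c18 (1.56), Sox11 (1.36), a transcription factor of progenitor cells, Pdgfra (1.28), U90926 (1.26), the placental hormone gene Prl2c2 (1.13) and the Wnt modulator Dact1 (1.12) were also higher. Obox3 (-2.72), Luzp4 (-2.60), Scarna17 (-2.13), Fgf14 (-2.03), Sprr1a (-2.03), Tspan18 (-1.79), Cd84 (-1.71) and H2-Q4 (-1.53) were lower, and 23 genes were at least 2-fold higher and 195 lower of 10943 kept. With genes kept at 5 or more these counts were 9 and 56. Sort1 was also high in WT, and Obox3, Luzp4 and Fgf14 also low there, so the limit given for them in P holds here too. MHC class I genes (median -0.80, percentile 0, 5 of 12 members at least 2-fold lower) and interferon response genes (-0.45, percentile 0, 5 of 30), with Tap1 at -1.68, Trim30a at -1.56, Irf7 at -1.33 and Ifi44 at -1.26, were lower than in EV. The limit given for the MHC class I list in P holds here too. AP-1 subunits were lower by their median (-0.18, percentile 0.55), with Jund at -0.51, Batf3 at -0.47 and Junb at -0.44 but Maf at 0.47, and inside the bounds by their mean (percentile 7.40). By rank on deposited values the genes were Sort1, Prex2, Megf10, Dgkg, Rnf144b, Jup, Rab40b and Acot1 at the upper end, and Obox3, Luzp4, Speer7-ps1, Rhox8, Scarna17, Fgf14, Rex2 and Sprr1a at the lower end.

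Wild-type cells differed most from EV. WT is a separate line, not made from the hypomorphic cells, and its label names no vector. Prep1 genotype, line of origin and infection therefore cannot be told apart where WT is compared with the other libraries. Gjb2, which encodes a gap-junction connexin, stood at 15.7 scaled units in EV and at 0.191 in WT. Sox2, a stem-cell transcription factor, stood at 12.1 and 0.610, Cthrc1, a secreted matrix-associated protein, at 10.2 and 0.0858, and Cck, the peptide hormone cholecystokinin, at 15.9 and 0.927. In the other direction Svep1, an extracellular matrix protein, stood at 10.2 in WT and 0.217 in EV, Sulf2, an extracellular sulfatase, at 11.4 and 0.282, Gnai1, a G-protein subunit, at 11.3 and 0.273, and Epha3, an ephrin receptor, at 9.30 and 0.248. Prelid2, Bnc1, Adam23 and Kctd15 were likewise among the highest, and Sorcs1, Klhl13 and Glt1d1 among the lowest. Added to these on the scaled values were Plxdc2 (3.39), Tnmd (3.21), Cpxm1 (3.19), Igsf10 (-3.05) and Bicd1 (-3.02).

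**Figure D3:**
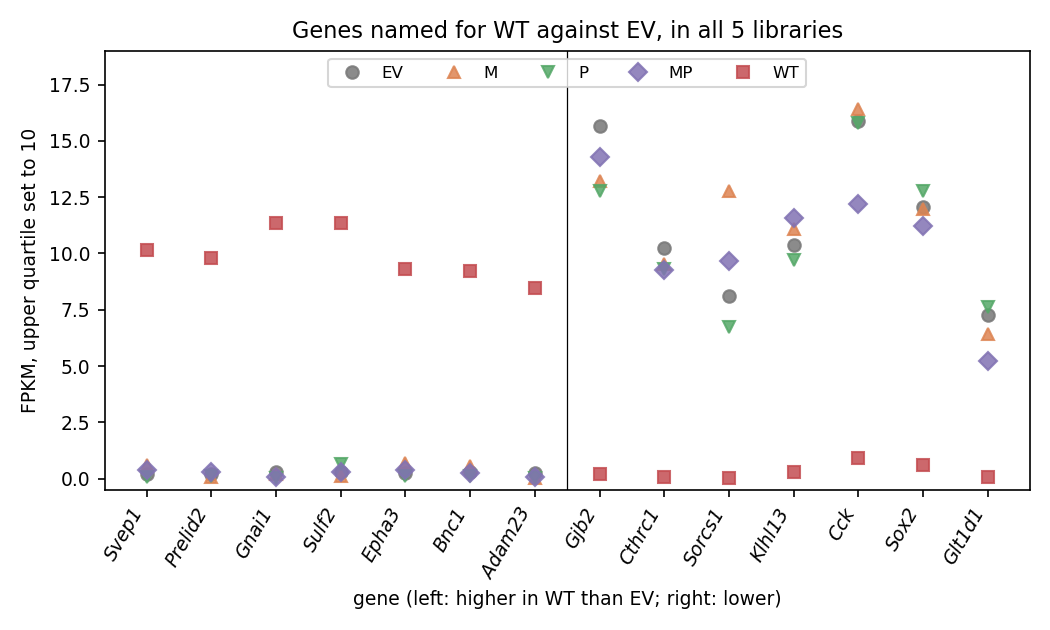
Levels of 14 genes named for WT against EV in all 5 libraries (FPKM after setting the upper quartile of genes to 10), with 1 point per library. The WT point stands apart from the 4 hypomorphic libraries at each gene: Gjb2 lies at 0.191 in WT and at 12.8 to 15.7 in the others.

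In all, 745 genes were at least 2-fold higher and 348 lower in WT than in EV, of 11566 kept. With P in place of EV as the reference, because of the level and receptor signal of EV, the counts were 725 and 210 of 11358. By a rule of at least 5 scaled units in WT and under 1 in each hypomorphic library, 97 genes were on in WT alone, among them Igf2, Gas6, Frzb, Sfrp2, Cxcl1 and Dpt, and 23 genes were off in WT alone, among them Tbx5, Irx1 and Pthlh.

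Wnt pathway genes were higher in WT (median log2 0.62 against 0.14 in matched random lists, percentile 100, 10 of 28 members at least 2-fold higher and 2 lower), with the secreted antagonists Frzb (3.03), Sfrp2 (2.70) and Dkk3 (2.36) and the ligand Wnt5b (2.41) highest and Axin2 lower (-1.67). Against P the list stood at 0.52, with 12 of 30 members at least 2-fold higher and 2 lower. IGF and growth factor genes were higher than in EV (0.36, percentile 99.9, 8 of 22 members at least 2-fold higher and 1 lower), led by Gas6 (3.09), Igf2 (2.91) and Fgf10 (1.91), with Pdgfd lower (-1.34). Against P that list stood inside the bounds by its median (0.03) but not by its mean (0.54, percentile 99.8), with 7 of 23 members at least 2-fold higher. Interferon response genes were lower in WT than EV (-1.02 against 0.22, percentile 0, 16 of 30 members at least 2-fold lower) and than P (-0.67, 10 of 28), with Usp18 (-2.81), Gbp3 (-2.77), Irf7 (-2.37) and Ifi44 (-2.34) lowest against EV. Cell cycle genes (-0.41 against -0.20 in matched random lists, percentile 0) had no 2-fold member, with Mcm6 at -0.79, Mcm4 at -0.76, Top2a at -0.74 and Uhrf1 at -0.71. Oxidative phosphorylation (-0.49, percentile 0), ribosomal protein (-0.40 against 0.04, percentile 0) and heat shock genes (-0.38, percentile 0.09) were lower as well. By their medians on scaled values these lists stood apart below EV in each of M, P, MP and WT. So did the cell cycle, interferon, MHC class I, histone, myofibroblast, extracellular matrix and glycolysis lists, all set against the same EV library. The 99th percentile over the upper quartile was 2.01 in EV, 1.98 in M, 1.88 in MP, 1.78 in P and 1.72 in WT. Oxidative phosphorylation medians fell in that order from M to WT (-0.13, -0.18, -0.35 and -0.49), whereas ribosomal protein medians did not (-0.27, -0.37, -0.18 and -0.40). Whether unequal compression gives these list differences was not tested, and matching on mean expression need not remove it. Inside the bounds were the MHC class I list in WT on deposited values (percentile 6.28) and, by their means, the myofibroblast list in WT (percentile 3.60) and the cell cycle list in MP (percentile 7.18). The extracellular matrix list was inside them in WT by its mean (24.8), and on deposited values in P (13.6) and WT (5.67). The glycolysis list was inside them by its mean in M (3.24), P (9.78), MP (9.31) and WT (15.9), and on deposited values in MP (6.90). For WT against P, the MHC class I (percentile 41.6), myofibroblast (percentile 25.1) and histone lists (percentile 24.9) were inside the bounds, and the heat shock list by its mean (percentile 2.61). So were the extracellular matrix (percentile 23.35) and glycolysis lists (percentile 7.64) by their medians. Fibroblast identity genes stood at 0.11 (against -0.09, percentile 98.3), with Islr at 2.55, Fap at 1.96, Pdgfra at 1.85 and Dpt at 1.82 and with Tbx15 lower at -1.56; this list stood at percentile 96.7 by its mean and 97.4 on deposited values, both inside the bounds.

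**Figure D4:**
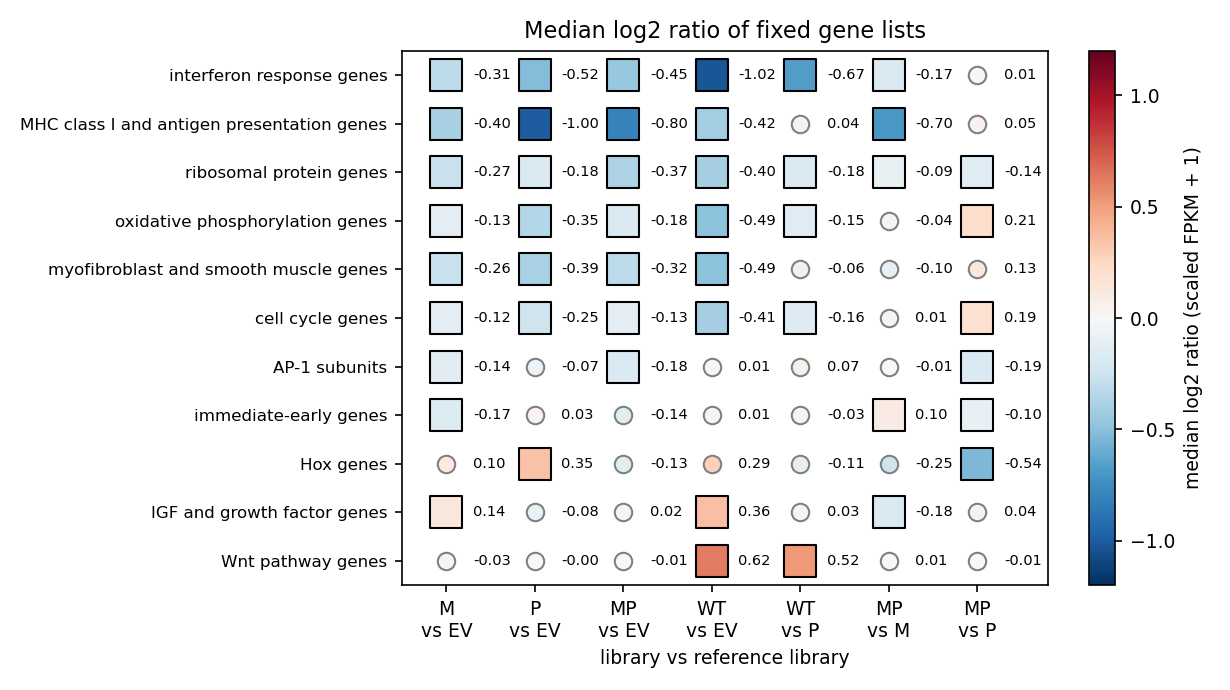
Median log2 ratio of 11 fixed gene lists in 7 pairs of libraries, on scaled values, printed beside each symbol. Squares mark lists that stood apart from matched random lists and circles those that did not: the lowest median is that of interferon response genes in WT against EV (-1.02) and the highest that of Wnt pathway genes in the same pair (0.62).

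The library labelled MP was compared with M to see what added Prep1 changes when Meis1 is also added, and with the library labelled P to see what added Meis1 changes when Prep1 is also added. These ratios were set across separately normalised tables. Against M, Sort1 (log2 2.05), Nemf (1.19), Sox11 (1.18), Igfbp5 (0.94) and Prl2c2 (0.90) were highest in MP, and Scarna10 (-1.90), Lrp1b (-1.19), the Wnt inhibitor Apcdd1 (-1.18), Tspan18 (-1.16) and Fgf14 (-1.14) lowest. MHC class I genes were lower in MP (-0.70, percentile 0, none of 9 members 2-fold), with Nlrc5 at -0.94, H2-Q4 at -0.85, H2-M3 at -0.79 and Tap1 at -0.78. Immediate-early genes (0.10, percentile 100), cholesterol synthesis genes (0.10, percentile 100) and AP-1-linked invasion genes (0.05, percentile 99.8) were higher by small amounts. Of 10796 genes kept, 22 were at least 2-fold higher and 127 lower in MP, and 2 and 18516 on deposited values. With scaled genes kept at 5 or more the counts were 5 and 15, so most of the lower genes had low values. The deposited ranking named Dact2, Rasl12, Jup, Whrn and Vmn1r44, and at the other end Pggt1b, Obox3, Akap4, Tspan18 and Lrp1b. Sort1, Jup, Fgf14, Pggt1b, Obox3 and Akap4 part EV and M from WT as well, so added Prep1 cannot be singled out at these genes. The limit given for the MHC class I list in P also holds for MP against M.

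Against P, the library labelled MP held more Pi15 (11.4 and 1.79 scaled units, log2 2.15), Kcnip1 (1.38), Stambp (1.37), B3galt1 (1.36) and Sfrp1 (1.36), a secreted Wnt antagonist, and less Scarna17 (-2.12), Scarna10 (-1.91), Wnt10b (-1.49) and Adam8 (-1.39). Cyp39a1 (1.27), Ppbp (-1.37) and Cda (-1.33) were added by rank on deposited values. Hox genes were lower in MP (median -0.54 against -0.13 in matched random lists, percentile 0.46, none of 8 members 2-fold), with Hoxc4 at -0.66, Hoxc9 at -0.64 and Hoxa4 at -0.59. AP-1 subunits were lower by their median (-0.19, percentile 2.35), with Batf3 at -0.96 but Fosb at 0.76 and Fos at 0.59, and inside the bounds by their mean (percentile 19). Cell cycle genes (0.19 against 0.11, percentile 99.8), with Top2a at 0.49 and Ccnb1 at 0.44, and oxidative phosphorylation genes (0.21, percentile 100) were higher. In all, 23 genes were at least 2-fold higher and 82 lower in MP of 10725 kept, and 26 and 93 on deposited values. On scaled values this pair leaves out EV and M, whereas the deposited ratios pass through the EV columns.

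All but Luzp4 of the 16 genes named for M over EV on scaled values moved the same way in MP over P. Higher in both were, for example, Pi15 (log2 1.18 and 2.15), Fgf10 (1.15 and 0.98) and Tnfsf11 (1.08 and 0.89), and lower in both were Acan (-1.64 and -0.91), Adam8 (-1.08 and -1.39) and Gchfr (-1.11 and -1.33). Sort1 and Igfbp5 were higher in both libraries labelled with added Prep1, in P over EV and in MP over M. Across 11227 genes, the Meis1 ratio without added Prep1 (M over EV) and with it (MP over P) correlated at Pearson r = 0.24 (Spearman rho = 0.23), and at r = -0.16 on deposited values. With each ratio centred on its median, the sign was shared by 57.5% of these genes and by 68.1% of the 94 that were 2-fold apart in M over EV. On deposited values it was shared by fewer, 40.0% of 20904 genes and 30.0% of the 5797 that were 2-fold apart. The Prep1 ratio without added Meis1 (P over EV) and with it (MP over M) correlated at r = 0.35 (rho = 0.21), and at 0.69 on deposited values. On scaled values the sign was likewise shared by 55.6% of genes and 83.8% of the 240 that were 2-fold apart in P over EV. Deposited values gave 88.8% of genes and 95.4% of the 4216 that were 2-fold apart. On scaled values these pairs of ratios share no library, but both Prep1 ratios set a library of low level against EV or M, so their correlation can reflect what EV and M share. The correlations are across genes, and genes are not independent replicates. Between M and P, both against EV, 6 genes were higher in both and 47 lower in both, where independent lists would share 0.215 and 1.04, and reassigning each gene's 3 values at random gave 18.2 and 38.7. The correlation was 0.34 against 0.50 on reassignment, and the covariance 0.0321 against 0.0552. The correlation, the covariance and the count higher in both thus lay under their reassigned values, and only the count lower in both lay above. EV, being 1 library, could not be split, so the excess over independent lists may come from the shared control.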

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

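Of the tests in this part, the sum of FPKM times transcript length as a test of scale, the share of the highest loci and the side taken by P at genes that part WT from the other lines were set before their results were seen, and the other tests were chosen after. Loci without a gene name, which the comparisons do not use, carried signal in every library: of 37277 such loci, 99.5% were above 0 in EV, 87.6% in M, 41.0% in P, 37.5% in MP and 42.7% in WT. These loci were singled out because they lie outside the comparisons.

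EV and M lay far above P, MP and WT at nearly every gene, with an upper quartile of 165 FPKM in EV and 12.0 in P. A few loci taking most of the signal would need over 90% of it in the 10 highest loci of P, MP and WT, and the highest share was 55.6%, in WT, which argues against this as the whole cause. FPKM times transcript length in kb, summed over 19953 genes, came to 2.98 times the largest sum that a scale set to the number of fragments allows in EV and 8.0 times in M, but to 0.201 of it in P, 0.175 in MP and 0.214 in WT. Prep1 level, low in EV and M by their labels, is argued against as the whole cause, because no change in expression takes that sum past its largest value (lower of EV and M, 2.98 times), and measured Pknox1 was lower in P (0.534) and MP (0.542) than in EV (2.06) and M (3.11). Values not scaled to the number of fragments remain a candidate explanation for these sums, and a smaller effect of Prep1 beneath a difference of scale is untested.

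Receptor genes of the nose carried signal in EV and M, with a median over 1396 genes of 0.268 scaled units in EV and 0.181 in M, and of 0 in P, MP and WT. Reads leaking from the other libraries are argued against, since at least 83.4% of these genes were listed at 0 in P, MP and WT. An additive floor from the authors' estimation is argued against as well, because the median of 9 Y-linked genes over that of receptor genes was 0 in EV. Of these genes, Uty (1.19 scaled units in EV) and Uba1y (1.12) nevertheless lay above the receptor median. Genomic DNA of the cells would also give a ratio of 0 in female cells, and it stays open: receptor genes on X stood at 2.07 times those on autosomes, outside the range of 0.67 to 1.5 set for it, but only 7 such genes lie on X. No biological explanation was tested for this signal.

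Pknox1 was not higher in P and MP. A swap of the P and WT labels is argued against: at 134 genes that part WT from EV, M and MP, P sided with the latter in 120 (89.6%) and with WT in 0, and Pknox1 in P was 26% of the EV level, where a wild-type library would lie above EV. The bound of 90% set beforehand was narrowly missed, since 14 genes lay between the levels, so the argument rests on the count of 0 and on Pknox1. That swap would also leave Pknox1 low in MP (0.542). Other exchanges of labels, such as EV with P together with M with MP, were not tested. Pknox1 was 3.85 times as high in EV as in P and 5.73 times as high in M as in MP. A compressed upper range is argued against, as the higher of the values in P and MP was 0.542, far below the upper quartile of 10. An introduced Prep1 transcript that was not counted at the Pknox1 locus, for example a coding sequence from another species, stays open, with Pknox1 in P at 5.0% of WT, because the construct is not given in the sources used here, and added Prep1 that was lost by the passage sequenced is untested too.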

How the results depend on the processing

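No paired analysis was possible because each group held 1 library. Scaling and centring decided most counts, since a whole-library shift passes the 2-fold rule as deposited and not after scaling. Of the alternatives below, upper-quartile scaling of lists, overlaps, correlations and named genes (with the status condition and without), upper-quartile scaling with genes kept at 5, P in place of EV, and centring of Meis1 and Pknox1 were chosen after seeing the data. Where no reason is given, the cause was not tested. Absolute depth is unknown and sets no limit that can be stated. If the commonest ratios at unnamed loci are single-read steps, 1 read weighs 3.68 times as many scaled units in M as in MP. For P and WT that factor is 0.540 and 0.712, so low values in M would rest on fewer reads. For EV no such factor was recovered.

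With log ratios centred on the median, genes higher and lower were 491 and 5555 in M than EV, 7228 and 105 in P, 7705 and 103 in MP, 7953 and 253 in WT, and 6891 and 30 in MP than M. Centring before scaling leaves genes near 0 far above the shifted centre, which makes them count as higher in the libraries of low level. With libraries scaled to their upper quartile they were 33 and 64 in M, 73 and 182 in P, 23 and 195 in MP, 745 and 348 in WT, and 22 and 127 in MP than M. With scaling and genes kept at 5 or more they were 13 and 23, 40 and 53, 9 and 56, 491 and 157, and 5 and 15, and 17 and 47 in MP than P. With P in place of EV, WT gave 725 and 210. Keeping deposited genes at 5 or more gave 896 lower in M than EV, 2 higher in P, 7 higher in WT, 0 higher in MP than M and 16 higher in MP than P, by removing low genes. A pseudocount of 0.1 gave 55 higher and 391 lower in MP than P. The other counts stayed within 1.5 times. The share of higher among called genes went from 83.3% to 34.0% with scaling and 8.12% with centring in M, from 0.0576% to 28.6% and 98.6% in P, from 0% to 10.6% and 98.7% in MP, from 0.0778% to 68.2% and 96.9% in WT, and from 0.0108% to 14.8% and 99.6% in MP against M.

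Genes higher in both M and P than EV numbered 8, and 14 with pseudocount 0.1 and 413 with centring. Those lower in both numbered 2577, and 1070 when kept at 5 or more, 49 with centring and 47 with scaling. The correlation of M and P differences from EV, -0.32 as deposited, was 0.44 with pseudocount 0.1, -0.0693 when kept at 5 or more and 0.34 with scaling. The Meis1 correlation (-0.16) was -0.0982 with pseudocount 0.1, -0.0819 when kept at 5 or more and 0.24 with scaling. The Prep1 correlation (0.69) was -0.0940 with pseudocount 0.1, 0.55 when kept at 5 or more and 0.35 with scaling. That of WT over EV with MP over M (0.59) was -0.0799, 0.47 and 0.12.

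The log2 ratio of Meis1 over EV was 0.94 with scaling and 1.08 with centring in M, 0.10 and 0.17 in P, 0.82 and 0.88 in MP, and 0.54 and 0.64 in WT, so it changed sign in P, MP and WT. That of Pknox1 was 0.43 and 0.63 in M, -0.99 and -0.69 in P, -0.99 and -0.57 in MP, and 1.93 and 2.40 in WT, where it changed sign. The direction of Pknox1 in P and MP did not.

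Of the genes named on deposited values, scaling named again 0 of 16 in M, 5 in P, 6 in MP and 2 of 10 in MP against M, each with the status condition kept or dropped, and pseudocount 0.1 named again 5 of 10 in MP against M. Of the authors' calls higher in WT, 6 of 11 were also 2-fold higher as deposited. Lists apart in MP against M numbered 7, and 11 with pseudocount 0.1 and 12 with means. Of 73 calls over 207 list and pair combinations, 13 were lost and 16 added with scaling among 192 compared, while 2 more calls kept too few members to compare, and lost and added were 14 and 12 with pseudocount 0.1, 10 and 6 when kept at 5 or more, 1 and 5 with no filter, 22 and 19 with means, and none turned direction.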

Other observations

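The tests in this part on genes that part WT from the hypomorphic lines were set before their results were seen, and the count of library splits was added after. Adipocyte genes were higher in WT than P (median log2 0.46, percentile 98.2, 4 of 10 members at least 2-fold higher) while against EV they stood inside the bounds by their median (percentile 96.9) and outside by their mean and on deposited values (99.7 each). Pparg, the regulator of fat cell formation, stood at 12.7 scaled units in WT, 1.33 in EV and 2.64 in P, and Lpl, lipoprotein lipase, at 5.13, 0.649 and 0.106. Chemokine and cytokine genes were lower in WT than EV (median log2 -0.31, percentile 0.09, 5 of 20 members at least 2-fold lower and 2 higher) and than P (-0.24, percentile 0.01), though on deposited values the list stood inside the bounds against EV (percentile 2.59). Ccl5 stood at 1.64 in WT and 14.3 in EV, Il1rn at 0.767 and 9.10, and Cxcl5 at 0.409 and 4.91, but Cxcl1 at 11.9 and 0.470. The next genes were chosen after their values were seen, from the AP-1-linked invasion list (percentile 3.43 against EV) and the imprinted list (percentile 51.4), both inside the bounds, although the invasion list stood outside them on deposited values (percentile 1.30). Mmp3 stood at 8.60 in WT, 0.356 in EV and 1.24 in P, whereas the growth factors Lif (3.16 and 9.33) and Areg (4.27 and 12.4) were lower in WT than EV. Of imprinted genes, Igf2 stood at 12.4 in WT and 0.784 in EV, H19 at 3.67 and 1.30, and Peg3 at 0.194 and 2.31.

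Genes that parted EV and M from the libraries labelled P, MP and WT by at least 2-fold were few. They were 16 higher in EV and M, among them Obox3, Fgf14, Dpp6 and Akap4, and 4 lower, namely Sort1, Jup, Pcsk6 and Pear1. Of the 10 ways to part 5 libraries 2 against 3, this one gave the most genes; the next, P and WT against the rest, gave 6 and 3. Sort1 stood at 0.817 in EV and 0.548 in M, against 5.52 in P, 5.43 in MP and 4.07 in WT. Jup, the junction protein plakoglobin, stood at 0.814 and 0.627 against 4.50, 3.51 and 7.78.

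A hypothesis that the libraries labelled with added Prep1 moved towards WT was tested at genes at least 4-fold apart between WT and a hypomorphic line, with libraries not used to choose the genes. EV and M nevertheless part together from P, MP and WT, at 16 genes higher and 4 lower. Genes that follow this split can count as towards WT, so the counts below are not independent of how the genes were chosen. For P over EV, the median log2 ratio signed towards WT was -0.00843 over 257 genes (quartiles -0.28 and 0.34), with 11 genes at least 2-fold towards WT and 1 away. For MP over M it was 0.0373 over 231 genes (quartiles -0.11 and 0.29), again with 11 and 1. Both medians lay under the bound of 0.1, but the members went both ways and Pknox1 was not higher in either library, so the hypothesis remains undecided.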
